A study of Homo sapiens with 4 samples.

How the data were processed

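The data were 4 protein-binding microarrays, on which a tagged protein is applied to double-stranded DNA on a glass surface and detected with a fluorescent antibody to the tag. Per the labels' protocols, full-length human proteins with an N-terminal GST tag were made in E. coli and purified, and binding was read with a fluorescent antibody to GST; the arrays held bound, unbound and test probes, each sequence on 6 spots. The labels name 2 replicate arrays of c-Myc with Max and do not say that they came from separate protein preparations, so p-values may measure technical spread only.

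The deposited scanner files hold 1 intensity per spot on a linear scale, whole numbers, for 180880 spots per array, of which 176022 belong to the sequences used here. Values above 65535, the ceiling of a 16-bit scanner, occurred at 399, 985, 1069 and 426 spots of the Max, c-Myc/Max replicate 1, Mad2/Max and c-Myc/Max replicate 2 arrays, and how scans were joined is not given in the sources used here. The files give no separate scans, background, outlier marks or slide, so the choice of a scan, the correction of background and saturated spots and a slide block, all named before the data were examined, did not apply; intensities were used as given. The deposited value table holds intensities that correlated, with r of 0.9999 on each array, with the median over the 6 spots after each was divided by the median of its 15 by 15 neighbours; this was found from the values, the table is linear and not normalized between arrays, and it served as an alternative. Median intensities of the value table were 1676 (Max), 2102 and 1962 (c-Myc/Max) and 2548 (Mad2/Max).

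The genomic part of a probe was 36 bp, followed by a 24-bp linker, and the site lay at positions 16 to 21. The level of a sequence was the median over its 6 spots of log2 intensity. Of the bound probes, 2711 (9.63%) had both sets of 3 spots on the same strand, and all of these carried a run of at least 4 G on the other strand; they were kept. Control spots, among them dark corners (median 237, 474, 473 and 490.5 in the array order above), served to describe the background. The dark corners were also subtracted from the intensities in an alternative added after the data were seen. Genomic positions and genes of the probes were not analysed here.

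Comparisons within an array used levels before normalization; comparisons between dimers used quantile normalization over all 29337 sequences. Bound probes were sorted by the first listed site found at the designed place on either strand: CACGTG, CACGCG, CATGTG, CACGAG, CATGCG, CACGTT, CACGTC, other CANNTG, or none. Classes with at least 10 members were tested. In class shifts a site class was set against the other bound probes, unbound probes against the bound probes, and probes with T next to CACGTG against probes of the same kind without T; non-CACGTG classes left out probes with a CACGTG elsewhere. Class differences used two-sided permutation tests of ranks over sequences with 100000 resamples (smallest p 1e-05) for the values reported and 2000 (smallest p 0.0005) for alternatives, with Benjamini-Hochberg adjustment. Sequences are not replicate arrays, so these tests describe the arrays at hand; shifts between dimers are set beside the shift between the c-Myc/Max arrays. CACGCG probes were also set against other bound probes of the same mean level of the dimers compared, in bins of 0.25 log2 with at least 20 probes of each kind, and standard errors of such differences came from 1000 bootstrap samples of the probes.

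Dimers were compared per sequence with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, 3 groups, 1 residual degree of freedom) at a Benjamini-Hochberg adjusted p under 0.05. On simulated data with 200 sequences changed among 29337, a log2 change of 1 was recovered in 80% for c-Myc/Max against Max and in 55.5% for Mad2/Max against Max, and changes of 2 and 3 in 100%. The simulation gave every array and every sequence 1 common spread, that between the c-Myc/Max arrays. In the data the spread can differ between sequences, and spots varied more on the Max and Mad2/Max arrays. Recovery in the data may therefore be lower. The permutation test called 2 of 100 simulated classes of 42 with no shift and 100 of 100 with a log2 shift of 1. Regression used ridge with 10 folds and, for stability selection, lasso on 100 random subsamples of the probes with the first 50 features each, keeping features chosen in at least 0.8 of them; on 28163 simulated sequences ridge gave an R squared of 0.492 where 0.5 was set, and 20 subsamples kept 8 of the 10 true features among 9 kept. Other steps used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and scikit-learn 1.9.0, and plots used matplotlib 3.10.9.

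The sequences named were fixed by a rule before the data were examined: all site and flank classes; the 5 highest and 5 lowest of the 10-bp test sequences by mean log2 level over the 4 arrays; for each comparison the 10 sequences with the largest gain and the 10 with the largest loss among those past the threshold with the same direction in both c-Myc/Max arrays; and the 5 highest and 5 lowest bound probes by mean normalized log2 level over the 4 arrays. Alternatives were the deposited value table, the mean of spots, median centring or cyclic loess, a filter on dim sequences (the 95th percentile of unbound probes), bound probes alone, spots as observations, leaving out each c-Myc/Max replicate, an effect size of at least 0.5, 5 folds and lasso. Others were added after the data were seen: subtraction of the dark corners, spots above the scanner ceiling left out, probes with both strands only, an intensity trend in eBayes, no CACGTG outside the site, and spots weighted by the spread of their array.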

Results

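Protein-binding microarrays measured how human Max, c-Myc with Max and Mad2 (Mxi1) with Max bound short human genomic sequences outside the cell. Max is a small DNA-binding protein that pairs with itself or with a partner, c-Myc is a transcriptional activator that binds DNA as a pair with Max, and Mad2 belongs to a family of repressors that compete with c-Myc for Max. The sites concerned are E-boxes, the 6-bp sequence CACGTG and its variants. There were 4 arrays in 3 groups: 1 array of Max at 100 nM, 2 arrays of c-Myc at 1 µM with Max at 100 nM, and 1 array of Mad2 at 1 µM with Max at 100 nM. Each array held 29337 sequences of 36 bp, each on 6 spots: 28163 bound probes (sequences from genomic regions bound in cells that hold a likely binding site), 900 unbound probes (genomic sequences chosen for the lack of such a site), test probes for the 136 distinct 10-bp sequences around CACGTG, and 18 test probes with a 12-bp sequence. The median intensity of the probe spots was 1753 on the Max array, 2151 and 1999 on the c-Myc/Max arrays and 2731 on the Mad2/Max array. The SD between spots within a set of 3 spots of a sequence was 0.61 (log2) on the Max array, 0.47 and 0.32 on the c-Myc/Max arrays and 0.51 on the Mad2/Max array. It leaves out the difference between the 2 sets of a sequence. For sets on opposite strands that difference had an SD of 0.89 for Max, 0.98 and 0.91 for c-Myc/Max and 0.81 for Mad2/Max. The number of arrays limits the precision: Max and Mad2/Max had 1 array each, so a difference between dimers cannot be told from a difference between arrays by replication. The arrays with c-Myc or Mad2 also held 1 µM of that protein beside the same 100 nM of Max. A difference from the Max array thus cannot be told from an effect of the amount of protein. Binding by Max paired with itself in these mixtures was not measured apart.

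The 2 c-Myc/Max arrays gave nearly the same profile. Over all sequences their log2 levels correlated with r = 0.978, and after quantile normalization the SD of their difference was 0.27. Arrays of different dimers correlated with r between 0.915 (Max against c-Myc/Max replicate 2) and 0.938 (c-Myc/Max replicate 1 against Mad2/Max), and their differences had an SD between 0.44 and 0.51. The correlations are across sequences, which are not independent replicates. A difference of 1 or more in log2 separated the c-Myc/Max arrays at 81 sequences, against 1519 and 1700 between Max and each c-Myc/Max array.

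The first comparison set genomic sequences with a likely site against those without. Per the labels the regions of both kinds had signal in cells, so the probes named unbound are defined by the lack of a site. The labels also say that bound and unbound probes were chosen by high or low scores of short sequences. A difference was thus favoured by the choice, and the p-values below are no independent evidence for it. Bound probes were brighter than unbound probes on every array. Their median intensity was 1706 on the Max array against 444.7 for unbound probes, a 3.84-fold difference; on the c-Myc/Max arrays the ratio was 2.71 and 2.42, and on the Mad2/Max array it was 2.22. Of the bound probes, 98.96% lay above the 95th percentile of the unbound probes on the Max array, 96.22% and 95.06% on the c-Myc/Max arrays and 83.53% on the Mad2/Max array. Bound probes with no CACGTG anywhere (n = 20831) were still 3.14-fold above unbound probes for Max, 2.23- and 2.01-fold for c-Myc/Max and 1.81-fold for Mad2/Max. The difference of medians was 1.94 (Max), 1.44 and 1.27 (c-Myc/Max) and 1.15 (Mad2/Max) on the log2 scale, with an SD of 1.15 to 1.38 among bound probes, and each had p = 1e-05 in a two-sided permutation test over sequences, the smallest that 100000 resamples can give (Benjamini-Hochberg adjusted p = 1e-05). With the dark corner spots subtracted as background the ratios were 7.14, 5.19, 4.44 and 3.03 for Max, c-Myc/Max replicates 1 and 2 and Mad2/Max, so their size depends on the background that is assumed.

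CACGTG, the canonical E-box, was the strongest site for every dimer. The 6897 bound probes with it at the designed site were 14.9-fold above unbound probes on the Max array, 10.0- and 7.91-fold on the c-Myc/Max arrays and 13.1-fold on the Mad2/Max array. With the dark corners subtracted these ratios were 31.1, 23.1, 17.8 and 21.2 in the same order. This put Mad2/Max below c-Myc/Max replicate 1. CATGTG was the brightest of the other listed site classes; CACGTG exceeded it 3.86-fold for Max, 3.91- and 3.51-fold for c-Myc/Max and 5.73-fold for Mad2/Max. CACGCG lay 5.49-fold below CACGTG for Max, 4.78- and 4.05-fold for c-Myc/Max and 8.26-fold for Mad2/Max. The 42 probes with CACGTC were the dimmest of the listed classes, 1.36-fold above unbound probes for Max and 1.11- to 1.16-fold on the other arrays.

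The other sites lay between these. CACGAG (n = 1852), CATGCG (n = 1365) and CACGTT (n = 745) were 2.97-, 2.58- and 2.92-fold above unbound probes on the Max array, and the 1739 probes with none of the listed sites were 2.66-fold above. On the Mad2/Max array the same classes were 1.69-, 1.6-, 1.67- and 1.46-fold above. Every class differed from CACGTG on every array at p = 1e-05 (permutation test over sequences, the smallest possible; 28 comparisons, adjusted p = 1e-05). The ratios over unbound probes depended on the background: with dark corners subtracted CATGTG stood 7.19-fold above them for Max, 4.80- and 4.06-fold for c-Myc/Max and 3.15-fold for Mad2/Max, CACGCG 4.71-, 3.66-, 3.31- and 1.98-fold, and on the Max array CACGAG, CATGCG, CACGTT and the probes with none of the listed sites 5.27-, 4.43-, 5.15- and 4.59-fold. With it CACGTG exceeded CACGTC 17.3-fold instead of 10.9-fold for Max, 16.6- and 13.7-fold instead of 8.63- and 7.06-fold for c-Myc/Max, and 17.9-fold instead of 11.8-fold for Mad2/Max. Sites of one class varied widely: within CACGTG, the 95th percentile was 8.66-fold above the 5th on the Max array, 12.7- and 10.9-fold on the c-Myc/Max arrays and 9.85-fold on the Mad2/Max array.

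The bases beside CACGTG changed its level many-fold in the test probes, which hold each of the 136 distinct 10-bp sequences in the same surroundings. The highest was ACCACGTGGT, with an intensity of 37770 for Max, 62270 and 47540 for c-Myc/Max and 81500 for Mad2/Max, followed in order of mean log2 level over the 4 arrays by ACCACGTGGG, ACCACGTGGC, GCCACGTGGC and TCCACGTGGA. The lowest was CTCACGTGAA, with 1229 for Max, 1309 and 1301 for c-Myc/Max and 2091 for Mad2/Max, and then by the same mean CACACGTGAA, ATCACGTGAA, GACACGTGAA and TTCACGTGAA. The range from lowest to highest was 30.7-fold for Max, 47.6- and 36.5-fold for c-Myc/Max and 39.0-fold for Mad2/Max. Within the pair of probes of a sequence and its reverse complement the SD was 0.23 to 0.38 (log2, root mean square over 120 pairs). The SD between sequences was 0.89 to 1.09.

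A T next to CACGTG, read on either strand, lowered the level on every array. The 58 sequences with such a T lay below the 78 without by -0.97 for Max, -1.63 and -1.62 for c-Myc/Max and -1.59 for Mad2/Max (difference of mean log2, p = 1e-05 in a two-sided permutation test, the smallest possible; adjusted p = 1e-05). The SD within either set was 0.56 to 0.82. A T at 1 half-site (n = 48) gave -0.90 for Max and -1.54, -1.54 and -1.46 for the c-Myc/Max and Mad2/Max arrays, and a T at both (n = 10) gave -1.3, -2.08, -2.03 and -2.21. The same contrast in the bound genomic probes, 2335 with T against 4422 without, was -0.79 for Max, -1.46 and -1.40 for c-Myc/Max and -1.36 for Mad2/Max. In an additive model per half-site, with G as the base compared with, C next to the site added 0.74 ± 0.08 (SE) for Max, 0.66 ± 0.08 and 0.64 ± 0.08 for c-Myc/Max and 0.87 ± 0.08 for Mad2/Max, while T took the level down by -0.48 ± 0.08, -1.03 ± 0.08, -1.04 ± 0.08 and -0.90 ± 0.08 in that order. An A at the second position out raised it by 0.34 to 0.48. The 18 sequences with 12 bp around CACGTG were all above the 95th percentile of the unbound probes on every array, with a median of 4547 for Max, 5503 and 4680 for c-Myc/Max and 10555 for Mad2/Max.

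The comparison of c-Myc/Max with Max asked which sequences were relatively brighter on the arrays of one than of the other. It cannot separate the dimer from the amount of protein. c-Myc/Max was relatively higher at CACGCG and CACGAG sites and relatively lower at CACGTG sites flanked by T. Of the 1885 sequences higher for c-Myc/Max, 686 (36.4%) had CACGCG, 572 had CACGTG, 318 had CATGTG, 153 had CACGAG and 101 had CATGCG. Of the 1911 sequences lower for c-Myc/Max, 1192 (62.4%) had CACGTG, 447 had CATGTG and 126 had none of the listed sites. Classes differ in size: the sequences higher were 11.9% of CACGCG, 8.29% of CACGTG, 3.26% of CATGTG, 8.26% of CACGAG and 7.4% of CATGCG probes. The sequences lower were 17.3% of CACGTG probes, 4.59% of CATGTG probes and 7.25% of those with none of the listed sites. Among CACGTG probes with T next to the site, 898 of 2335 (38.5%) were lower and 16 higher, against 261 of 4422 (5.9%) lower and 546 (12.3%) higher without T. That share higher was near the 11.9% of CACGCG probes and above the 8.26% of CACGAG probes. Of the test probes with a 10-bp sequence, 64 (25.0%) were lower and 9 higher.

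As classes, with each site class set against the other bound probes, probes with CACGCG shifted by 0.22 towards c-Myc/Max (log2 difference of medians, n = 5710), those with CACGAG by 0.22 and those with CATGCG by 0.19. Probes with CACGTG shifted by -0.16, those with CATGTG by -0.10, those with CACGTT by -0.12 and those with none of the listed sites by -0.20. The classes with T were set against probes of the same kind without T, so their values are not on the same footing: the 10-bp test probes with T shifted by -0.67 (n = 112), and bound CACGTG probes with T by -0.62. Each of these had p = 1e-05 in a permutation test over sequences (adjusted p = 1.2e-05 over 33 tests; the smallest possible). The CACGTC shift did not pass (-0.00185, n = 42, permutation p = 0.49), and its sign changed with the processing: it was 0.41 under median centring, 0.15 with cyclic loess and 0.11 with bound probes alone. Unbound probes, set against the bound probes, shifted by 0.06, and by 0.57 under median centring. The same values between the 2 c-Myc/Max arrays were -0.05 for CACGCG, 0.02 for CACGTG, 0.07 for the test probes with T and 0.03 for the bound probes with T. Those of CACGCG and CACGTG also had p = 1e-05 in the permutation test, so a shift is to be read by its size beside the replicate shift.

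The sequences with the largest relative gain in c-Myc/Max were 10 probes with log2 differences of 2.53 to 3.26. Of these, 9 had CACGCG and 7 had both sets of 3 spots on one strand. Of the 9, 7 read CCACGCGG on either strand, with a C before each half-site on its own strand. The first was Bound_023002_111_111 (site and neighbours AGCCGCGTGGAC), with an intensity of 1069 for Max and 12986 and 10412 for c-Myc/Max, a difference of 3.26 ± 0.189 (SE; limma adjusted p = 0.000166). The next was Bound_007777_001_000 (CCCCGCGTGGGG), with 5470 for Max and 64246 and 58750 for c-Myc/Max, a difference of 3.07 ± 0.195 (limma adjusted p = 0.000166). With the value table these differences were 2.59 for Bound_023002_111_111 and 2.95 for Bound_007777_001_000. The 10 with the largest relative loss, from -2.83 to -1.96, all had CACGTG with T next to it. The first was Bound_009693_111_001 (CTCCACGTGACT), with 23124 for Max and 4153 and 4139 for c-Myc/Max, a difference of -2.83 ± 0.196 (limma adjusted p = 0.000305). With the value table this difference was -2.04.

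These counts came from limma on quantile-normalized levels with adjusted p under 0.05, where 8577 of 29337 sequences had an unadjusted p under 0.05. The fit had 1 residual degree of freedom, from the c-Myc/Max arrays, and took the Max array to vary like them, though its spots varied more; under other processing the number higher ranged from 885 to 3617 and the number lower from 1023 to 3670.

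Between Mad2/Max and Max, of 562 sequences higher for Mad2/Max among the 29337, 383 (68.1%) had CACGTG and 87 had CATGTG. They were 5.55% of CACGTG and 0.893% of CATGTG probes. Of 597 lower, 336 (56.3%) had CACGTG, 98 had CATGTG and 82 had CACGCG. These were 4.87% of CACGTG, 1.01% of CATGTG and 1.42% of CACGCG probes. Among CACGTG probes with T next to the site, 203 of 2335 were lower and 17 higher, and without T 116 of 4422 were lower and 361 higher. Against probes of the same kind without T, the bound CACGTG probes with T shifted by -0.40 and the test probes with T by -0.25 (each p = 1e-05, permutation test over sequences, the smallest possible), while against the other bound probes the shifts of CACGTG (0.06), CACGCG (-0.04), CATGTG (0.02), CACGAG (-0.03), CATGCG (0.09), CACGTT (-0.04) and CACGTC (0.09) were small; that of CACGCG was no larger than between the c-Myc/Max arrays (-0.05). Probes with none of the listed sites shifted by -0.11, and unbound probes by 0.17 against the bound probes. The first of the 10 sequences with the largest gain was Bound_025082_001_000 (ACCCACGTGGGC), with 8291 for Max and 72257, above the scanner ceiling, for Mad2/Max, a difference of 2.36 ± 0.231 (limma adjusted p = 0.0104). With the value table this difference was 1.86. Of the 10 gains, 8 had CACGTG. Of the 10 with the largest loss, from -2.19 to -1.83, 6 had CACGTG and all 6 had T next to it. With weighted spots 9 of the 10 gains and 7 of the 10 losses had an adjusted p under 0.05 in limma.

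Both arms of this comparison were single arrays, so the limma fit rests on the spread of the c-Myc/Max arrays alone, and only 156 of its 1159 calls were also called when spots were weighted by the spread of their own array. Under other processing the number higher ranged from 90 to 3289 and the number lower from 89 to 2031. They were 150 and 173 when spots above the scanner ceiling were left out. Under median centring 3289 were higher and 461 lower (87.7% higher, against 48.5%), the median of all sequences moved to 0.14, and the shifts were 0.44 for CACGTG, -0.57 for the test probes with T, -0.10 for CACGCG and for CATGTG, -0.12 for CACGAG (-0.00642 with cyclic loess, permutation p = 0.27), -0.13 for CACGTT, 0.48 for CACGTC (0.00203 with the value table, permutation p = 0.33), 0.67 for unbound probes and 0.01 for CATGCG (permutation p = 0.74).

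Between c-Myc/Max and Mad2/Max, CACGCG and CACGAG sites were relatively higher for c-Myc/Max and CACGTG sites relatively higher for Mad2/Max. Of 1086 sequences higher for c-Myc/Max among the 29337, 594 (54.7%) had CACGCG, 155 had CACGTG, 143 had CATGTG and 113 had CACGAG. They were 10.3% of CACGCG, 2.25% of CACGTG, 1.47% of CATGTG and 6.1% of CACGAG probes. Of 780 lower, 633 (81.2%) had CACGTG, which is 9.18% of that class. The CACGCG class shifted by 0.28 towards c-Myc/Max, CACGAG by 0.26, CATGCG by 0.12 and CACGTG by -0.22, and CATGTG, CACGTT and probes with none of the listed sites by -0.13, -0.09 and -0.07, against -0.05, 0.01, -0.02 and 0.02 for the first 4 between the c-Myc/Max arrays (each p = 1e-05, permutation test over sequences, the smallest possible). The 10 sequences with the largest gain for c-Myc/Max, from 2.37 to 2.97, all read CCACGCGG on either strand, and 9 had both spot sets on one strand. The first was Bound_007777_001_000, with 64246 and 58750 for c-Myc/Max and 13406 for Mad2/Max, a difference of 2.97 ± 0.195 (limma adjusted p = 0.000563). With the value table this difference was 2.99. Of the 10 with the largest loss, from -2.11 to -1.59, 8 had CACGTG and 2 had CATGTG. The first was Bound_012417_011_001 (TTTCACGTGGGT), with 4269 and 2877 for c-Myc/Max and 26050 for Mad2/Max, a difference of -2.11 ± 0.227 (limma adjusted p = 0.00173). With the value table this difference was -1.71.

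The T-flank shift of this comparison, -0.40 in the test probes against those without T, depended on the normalization: under median centring it was -0.09 (p = 0.33, permutation test). Within arrays the T difference was -1.59 for Mad2/Max and -1.63 and -1.62 for c-Myc/Max; in bound probes the shift went from -0.25 to -0.04. Under other processing the number higher ranged from 505 (spots above the scanner ceiling left out) to 2687 (mean of spots) and the number lower from 328 to 3704. Median centring gave 937 higher and 3704 lower (20.2% higher, against 58.2%), moved the median of all sequences to -0.12, and gave shifts of -0.62 for CACGTG, 0.20 for CATGCG, -0.04 for CATGTG, 0.00202 for CACGTT (permutation p = 0.21) and 0.0135 for probes with none of the listed sites.

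The series concerns regression models of binding specificity, so the level of the bound probes was predicted from their sequence. The site class alone explained 62.1% of the variance of log2 intensity for Max, 52.3% and 50.9% for c-Myc/Max and 68.9% for Mad2/Max. Single bases by position raised this to 71.1%, 67.3%, 65.8% and 78.6%, dinucleotides to 76.8%, 72.7%, 71.3% and 82.2%, and trinucleotides to 79.5%, 75.1%, 74.0% and 83.9% in the order Max, c-Myc/Max replicates 1 and 2, Mad2/Max. Within CACGTG probes alone the full model had an R squared of 0.549, 0.591, 0.588 and 0.661. These are values of ridge regression predicted for probes held out of the fit, over 28163 probes in 10 folds; the squared correlation of the 2 c-Myc/Max arrays over the same probes was 0.953.

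Stability selection kept 34 sequence features for Max, 31 and 33 for the c-Myc/Max arrays and 31 for Mad2/Max out of 2441 offered. Of the 51 kept on at least 1 array, 15 were kept on all 4, among them the CACGTG class, ACC and CCA running into the start of the site and GTG at its end with positive sign, and AA directly after it with negative sign. The c-Myc/Max arrays had 31 kept features in common. An A directly after the site was chosen as a single base, with negative sign, in every subsample for c-Myc/Max and Mad2/Max and in none for Max. For Max the longer features AA and AG at positions 22 to 23, which begin with this base, were chosen in every subsample with negative sign. AC at positions 13 to 14 was kept for Mad2/Max only. Whether selection frequencies differ between dimers was not tested.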

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

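The tests of explanations in this part were chosen after the result they bear on was seen; the limits of the one on a further E-box-like site were set before its value was known, but after the other tests of strands had been run; the size limits for listing a shift (at least 0.2, and more than 3 times the replicate shift) were also set after the shifts were seen. The limits of the test on the Max array were rewritten once its first value, -0.404, was known, because the median centred value pointed elsewhere, and the tests on dim probes and on a strand effect were replaced, once values of single classes were known, by tests over all levels and all site classes.

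Sequences with T next to CACGTG differed between dimers from probes of the same kind without T, by the permutation test of the difference: the test probes shifted by -0.673 for c-Myc/Max against Max, -0.25 for Mad2/Max against Max and -0.404 for c-Myc/Max against Mad2/Max, and bound probes by -0.619, -0.399 and -0.254. Brightness trends across the array are argued against, since the shift against Max was -0.637 after division by the local median. So is a compression of the whole Max scale, since CACGTG stood above unbound probes by 0.75 log2 more there than on the c-Myc/Max arrays. That contrast includes the background, so it cannot decide on compression among CACGTG probes alone. Among these the 95th percentile was 8.66-fold above the 5th for Max, against 12.7- and 10.9-fold for c-Myc/Max. This spread includes the T difference itself. In the test probes C next to the site added 0.74 per half-site for Max and 0.66 and 0.64 for c-Myc/Max. An odd Max array as the whole cause cannot be told apart from a difference between dimers, and no second Max array was analysed here. The contrast of c-Myc/Max with Mad2/Max gave -0.0908 under median centring and -0.404 under quantile normalization. That quantile normalization included the Max array, so -0.404 is not free of it. Within arrays, before normalization, the T difference of the test probes was -1.63 and -1.62 for c-Myc/Max and -1.59 for Mad2/Max. A difference between the dimers, which the design names, stays open. It was not tested apart from the arrays or, against Max, from the amount of protein.

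By the same test, against the other bound probes, CACGCG probes shifted towards c-Myc/Max by 0.224 against Max and 0.278 against Mad2/Max. Among probes with sets on opposite strands, the shift against Max held on each strand reading, the smaller being 0.178. For these probes that argues against spots of one strand alone. Probes with both sets on one strand shifted by 0.0869 where the site read CACGCG (n = 475) and by 0.187 where it read CGCGTG (n = 381). These values were not tested. A common rise of dim probes as the whole cause is argued against, since CACGCG probes stood above other bound probes of the same mean level. Under median centring they did so by 0.262 ± 0.008 (bootstrap SE) against Max and 0.327 ± 0.0084 against Mad2/Max, each smaller than under quantile normalization. Cyclic loess gave 0.258 and 0.328. With other bound probes without CACGTG as the comparison set, median centring gave 0.234 and 0.294 and cyclic loess 0.231 and 0.297. The dimmest probes did shift towards c-Myc/Max against Max under median centring, CACGTC by 0.411 and unbound probes by 0.57, but against Mad2/Max they shifted by -0.0346 and -0.0972. Probes reading CCACGCGG on either strand shifted by 0.412 more than the other CACGCG probes against Max, so the flank may carry part of the difference. With 1 array each of Max and Mad2/Max, array and dimer remain confounded, as does the amount of protein against Max.

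The 2 strands of a sequence gave different levels, and the difference repeated between arrays. Noise between spots is argued against, because the difference correlated between the c-Myc/Max arrays by 0.58 more for sets on opposite strands than for sets on one strand; a fixed effect of spot position is argued against by a repeatable SD 4.2 times as large. A further E-box-like site nearer the linker on one strand may account for part, as the SD was 0.75 times as large in CACGTG probes without one, between the limits set, so its share stays open. A strand effect of equal size on every array, as the whole cause, is argued against by CACGAG, whose difference between readings lay -0.152 ± 0.019 and -0.187 ± 0.018 (bootstrap SE) from that of Max on the c-Myc/Max arrays. The other 4 site classes tested, with gaps of -0.0749 to 0.0572, did not pass the limits set. Among them the small gaps of CATGTG (-0.0615 ± 0.0089 and -0.0749 ± 0.0083) and CACGCG (0.044 ± 0.016 and 0.0503 ± 0.014) still lay beyond their SE from equality. Array, dimer and, against Max, the amount of protein are confounded. No biological explanation was tested.

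By the same test, against the other bound probes, CACGTG probes shifted by -0.225 between c-Myc/Max and Mad2/Max. CACGAG probes shifted by 0.222 for c-Myc/Max against Max and 0.256 against Mad2/Max. Control spots named E1A, outside the comparisons, were brighter than negative-control spots by 1.41-fold on the Max array, 1.19- and 1.13-fold on the c-Myc/Max arrays and 1.18-fold on the Mad2/Max array.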

How the results depend on the processing

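The tests with dark corners subtracted, spots above the scanner ceiling left out, opposite-strand probes, an intensity trend, no CACGTG outside the site and weighted spots were chosen only after the data were seen. Of 597 alternative values, 545 were kept (392 of 426 chosen beforehand, 153 of 171 added). Kept means the same direction and side of the threshold. For counts and the replicate SD it means within 1.5 times, and for R squared a change under 0.05. All were kept for bound against unbound probes (16), site classes (128), flanking bases (16), the c-Myc/Max replicates (9) and regression (48), and 284 of 302 class shifts were. With so many sequences per class, a kept shift can still change much in size. Under median centring the CACGTG shift went from 0.06 to 0.44 for Mad2/Max against Max and from -0.225 to -0.625 for c-Myc/Max against Mad2/Max. The alternatives on scans, background, saturation and slide that were named beforehand were not run, since the files hold 1 intensity per spot. With 1 c-Myc/Max array left out no residual degree of freedom remains for the counts of calls, and the signs of called sequences say nothing about stability, since the calls were selected by the spread of these arrays. No paired analysis was possible because the groups share fewer than 2 replicate numbers. Signal over background limits dim classes most on the Mad2/Max array, where 83.53% of bound probes lay above the 95th percentile of unbound probes.

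Median centring reversed the CATGTG shift of Mad2/Max against Max (-0.0959), and the CACGTT shift (0.00202) and that of probes with none of the listed sites (0.0135) for c-Myc/Max against Mad2/Max. The CACGTC shift of c-Myc/Max against Max, which did not pass (-0.00185), has no settled sign: it was 0.411 with median centring, 0.147 with cyclic loess, 0.115 with bright sequences, 0.11 with bound probes alone, 0.0413 with the value table, 0.000287 with the mean of spots and 0.00513 to 0.0479 with 1 c-Myc/Max replicate left out. Median centring ended the call of the test probes with T for c-Myc/Max against Mad2/Max (-0.0908). The cause was not tested.

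For c-Myc/Max against Max, sequences higher numbered 3617 with the mean of spots and 885 with weighted spots; sequences lower numbered 3225 with the value table, 3670 with the mean of spots, 2898 with an intensity trend and 1023 with weighted spots. For Mad2/Max against Max, higher and lower calls numbered 2037 and 2031 with the mean of spots, 1183 and 1297 with cyclic loess, 1413 and 1533 with an intensity trend, 1057 and 1127 with dark corners subtracted, 150 and 173 without spots above the ceiling, 358 and 388 with opposite-strand probes, 354 and 360 with spots as observations, and 90 and 89 with weighted spots; median centring gave 3289 higher. For c-Myc/Max against Mad2/Max they numbered 2472 and 2456 with the value table, 2687 and 2516 with the mean of spots, 1700 and 1245 with cyclic loess, 2015 and 1561 with an intensity trend, and 505 and 328 without spots above the ceiling; median centring gave 3704 lower. The cause was not tested. The effect size filter removed no call.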

Other observations

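All tests in this part were chosen only after the data were seen. A second copy of CACGTG went with a higher level. The 134 bound probes with 2 copies were brighter than the 6757 with 1 copy by 2.64-fold on the Max array, 2.54- and 2.76-fold on the c-Myc/Max arrays and 2.18-fold on the Mad2/Max array (adjusted p = 1.3e-05, permutation test over sequences, from the smallest p possible). The 6 probes with 3 copies had a median intensity of 43466 for Max. By mean normalized log2 level over the 4 arrays, the 5 brightest bound probes were Bound_011148_111_000, Bound_009195_111_010, Bound_018589_010_000, Bound_010210_000_010 and Bound_018829_110_000. Of these, Bound_010210_000_010 holds 3 copies and reached 101889, above the scanner ceiling, for Max. The others hold 1 copy each, which in Bound_011148_111_000 lies outside the designed place, where the site is CATGTG. The 5 dimmest by this mean were Bound_001841_001_001, Bound_005151_001_000, Bound_028001_001_001, Bound_001753_001_001 and Bound_003791_001_001, 4 of them with CACGTC.

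The place of CACGTG along the probe mattered. In 394 bound probes with sets on opposite strands, the only CACGTG lay off the designed place. It was sorted by its side of that place, at any distance. The strand with it on the side away from the linker was brighter than the strand with it on the linker side. The difference was 2.43 log2 for Max, 2.23 and 2.28 for c-Myc/Max and 2.20 for Mad2/Max. It went that way in 91.9%, 89.6%, 87.8% and 90.1% of the probes (p = 1e-05, permutation of signs, the smallest possible). On the Max array the medians were 18446 and 2728. Probes reading CCACGCGG on either strand (n = 979) were brighter than other CACGCG probes (n = 4731) by 1.74-fold for Max, 2.17- and 2.2-fold for c-Myc/Max and 1.62-fold for Mad2/Max.

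Of the 10 sequences with the largest gain of c-Myc/Max over Max, 7 had both spot sets on one strand, and so had 9 of the 10 with the largest gain over Mad2/Max, against 9.63% of all bound probes. Among all bound probes called in these 3 comparisons the share was 10.9% to 12.3% per direction, except 120 of 748 for those lower in c-Myc/Max than in Mad2/Max.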
